A study of Homo sapiens with 30 samples.

How the data were processed

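Gene expression was measured by RNA sequencing in HEY-A8, a human ovarian cancer cell line, cultured on Matrigel or on heat-denatured Matrigel for 2, 8, 24 or 48 h. Per the labels' protocols, cells kept in DMEM/F-12 with 10% serum were plated on the gel for 1 h and then given RPMI1640 with 15% serum. The control gel had been exposed to dry heat at 65 °C for 10 min. RNA was extracted with TRIzol and sequenced from poly-A libraries prepared by a sequencing company. The labels placed 30 libraries in 8 groups, with 3 libraries on Matrigel at 2 h and at 8 h and 4 libraries in each other group. Nothing in the labels says that replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

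The deposited table of each sample gives 1 expected count and 1 FPKM value (fragments scaled by transcript length and library size) per gene, per the file headers. An expected count is an estimate that need not be whole, and 17.6% to 19.7% of the values in a library were not whole. FPKM values were computed by the authors before deposit and were used for levels and for an alternative test. The genome build was hg38 per the submitters' processing notes. The aligner, the counting program, the annotation version and the use of strand are not given in the sources used here. The files held only genes with a value above 0 in that library. In all, 17367 genes were listed in at least 1 library, of which 17337 matched the reference gene table that supplied symbols and hg38 coordinates. Genes of the mitochondrial genome were not analysed here. Totals were 15.62 M to 18.55 M expected counts per library. In 42 comparisons of replicates, counts differed by more than sampling noise (chi-square over degrees of freedom of 3.07 to 40.6), and 0 pairs of libraries were identical. Each library was counted as 1 sample, but this does not show that libraries were independent. Replicates 1 and 2 were close in every group that held both (3.07 to 8.03), as were replicates 3 and 4 at 48 h (5.61 and 4.67). All other comparisons at 2 and 8 h gave 19.8 to 40.6.

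Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (quasi-likelihood test) in R 4.3.3, with TMM factors of 0.952 to 1.04 and the default filterByExpr filter on the 8 groups, which kept 12922 genes. All 30 libraries entered 1 fit with a mean for each of the 8 groups and 22 residual degrees of freedom. The comparisons were Matrigel against denatured Matrigel at each time, the change of that difference between times, and each time step within a matrix. P-values were adjusted by the Benjamini-Hochberg method at 0.05. Log2 differences are Matrigel minus denatured Matrigel, or later minus earlier time, and are given with their standard error. The groups, this test, its alternatives, the gene lists and the rule for naming genes from this test were fixed before the data were examined.

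The labels give replicate numbers that recur across groups. Whether they pair the libraries was checked from the correlation between deviations from the group means. Within a time, libraries with the same number on the 2 matrices correlated at 0.325 to 0.626 at 2 h, 0.341 to 0.484 at 8 h, 0.103 to 0.277 at 24 h and 0.139 to 0.311 at 48 h. All pairs were above the fixed minimum of 0.1, the lowest at 24 h only just. A library correlated best with its own number in 6 of 6, 6 of 6, 8 of 8 and 4 of 8 cases at the 4 times. This measure was fixed beforehand, but gene calls of both fits had been seen before its values were computed. The pairing comes from the data and the numbering alone, since the labels do not state a shared day or batch. The fit with a replicate block within time (10 residual degrees of freedom) was among the alternatives fixed at the start. It was also treated as a result of its own after its calls had been seen, and its values are named as paired. Libraries without a partner, which were denatured replicate 4 at 2 h and denatured replicate 2 at 8 h, carry no weight in a paired difference.

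Gene lists on 39 topics (vessel-forming tumour cells, matrix and adhesion, stress responses, metabolism, growth, signalling and markers of other cells) were written from textbook knowledge. Of their 1030 symbols, 989 were found. The 37 lists with at least 5 tested members were compared with all other genes by camera (edgeR and limma 3.58.1) at a preset correlation of 0.01, adjusted over lists and the 4 times together. Repeats with an estimated correlation, and with fry, were alternatives.

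Genes were named by rule. For each matrix difference these were the 10 highest and 10 lowest log2 values past the threshold with a symbol, a mean of at least 5 FPKM in the higher group and no overlap between groups. In the paired result, the same direction in every pair, in normalized log2 counts, took the place of no overlap. Naming genes from the paired result was decided after its calls had been seen. Up to 4 members past the threshold were taken from each described list at 1 FPKM or more. Genes with the same sign at all 4 times (5 each way), for each change the 4 highest and 4 lowest, and for each time step the 3 highest and 3 lowest completed the rule. The tested genes of the vasculogenic mimicry list were also named. The results of a few genes that met these rules are not reported here. Ribosomal protein pseudogenes and genes with a locus number for a name were left out of the top lists.

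Alternatives were DESeq2 size factors, DESeq2 1.42.0, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for 11243 genes at 1 FPKM or more in at least 3 libraries, no low-count filter (17348 genes), a mean of at least 100 counts (9877 genes), only the groups compared, an additive replicate block (19 residual degrees of freedom) and leaving out each library in turn. A correction for transcript length and GC content (splines with 5 degrees of freedom in each library) was added later. Leaving out both replicate 3 libraries of a time was chosen after seeing the data. Fold changes on log2(FPKM + pseudocount) understate changes of low genes.

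The steps were tested on simulated counts with 200 genes changed. For the matrix difference at 24 h, the unpaired fit recovered 84.7% of genes changed by a log2 of 1 and 61% of those changed by 0.5 (12819 genes), and the paired fit 89.9% and 67.7% (12825 genes). At 8 h the unpaired fit recovered 84.7% and 54%. Wrong calls numbered at most 14 in the runs of all comparisons. The unpaired fit at 2 h gave 14, and recovered 86.7% of 98 genes changed by 1 and 50% of 100 changed by 0.5. Its share of wrong calls was thus above the 0.05 aimed at. The unpaired runs drew libraries independently around their group means. Real libraries with the same number deviated together, so wrong calls from such structure were not measured. On simulated libraries of 12922 genes, the changed list was found in 6 of 6 runs, and at most 2 of 136 tests of unrelated lists were called. The runs were unpaired or paired, each by camera with the preset or an estimated correlation, or by fry. Genes were drawn independently, so wrong calls among correlated genes were not measured. A simulated GC trend called 2381 genes before the correction and 0 after it.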

Results

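HEY-A8 is a human ovarian cancer cell line, and on Matrigel, a gel of basement membrane proteins, such cells can form vessel-like networks without endothelial cells. This is called vasculogenic mimicry. Heat-denatured Matrigel was the control surface, per the labels. Expression of 30 libraries was compared between the surfaces at 2, 8, 24 and 48 h, with 3 libraries on Matrigel at 2 h and at 8 h and 4 in every other group. Time after seeding separated the libraries far more than the surface did. The first principal component held 54.2% of the variance and placed the 2 h libraries at -76.4 to -62.1 and all later ones at 5.6 to 34.3. Components 2 and 3 held 13% and 4.66%. On component 3, replicate 3 at 2 h lay at -26.8 and -29.2 on the 2 matrices and denatured replicate 4 at -13.5, while replicates 1 and 2 at 2 h lay at 13.2 to 20.6. Replicate 3 at 8 h lay at -15.7 and -17.1. At 2 and 8 h libraries thus stood apart together with their same-number partner on the other matrix. A paired test within each time is given beside the unpaired test of all libraries. The ground for pairing was less clear at 48 h, where only 4 of 8 libraries correlated best with their own number.

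At 2 h, cells on Matrigel expressed far more of the inducible heat shock genes. HSPA6, an HSP70 made almost only under stress (chromosome 1, 161524540 to 161526894 on hg38), was at 49.6 ± 18.3 FPKM against 0.425 ± 0.411 (log2 6.86 ± 0.35, adjusted p 1.91e-13). HSPA1A and HSPA1B, the main inducible HSP70 genes, were higher by 2.04 ± 0.15 and 2.02 ± 0.14 (adjusted p 6.13e-10 and 2.11e-10). They lie side by side on chromosome 6, from 31815543 and from 31827738, and their sequences are so alike that reads may be shared between them. The co-chaperone DNAJB1 reached 143 ± 18.6 against 73.1 ± 8.2 FPKM (0.99 ± 0.10, 6.92e-07), and HSPH1, which recharges HSP70, was higher by 0.65 ± 0.10 (0.000533). In the list of 20 heat shock proteins, 4 were higher and 0 lower, or 8 when adjusted over the list alone, and the list test gave an adjusted p of 7.18e-28 (0.00642 with an estimated correlation). With pairing, 11 were higher (14 over the list alone), among them the small chaperone CRYAB (1.47 ± 0.41, 0.0418), and the list p was 1.1e-51 (0.000588).

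**Figure D1:**
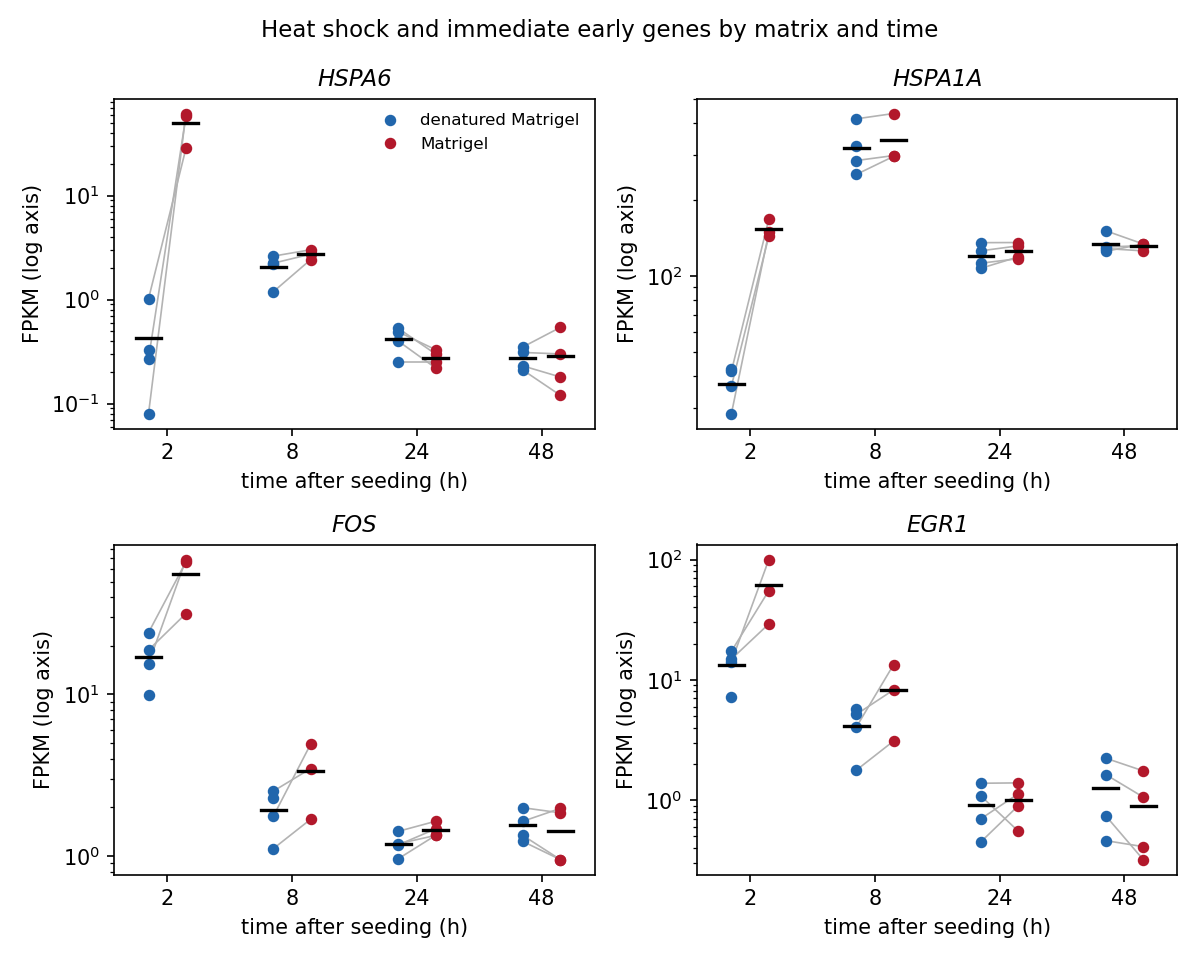
FPKM of 2 heat shock genes (HSPA6, HSPA1A) and 2 immediate early genes (FOS, EGR1) on a log axis. Each point is a library, black bars are group means and grey lines join libraries with the same replicate number within a time.

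Immediate early genes, which answer growth factor and stress signals within minutes, were also higher on Matrigel at 2 h. The transcription factors EGR1 (61.6 ± 35.9 against 13.4 ± 4.30 FPKM, 2.22 ± 0.43, adjusted p 0.00891) and FOS (55.5 ± 20.6 against 17.1 ± 5.96, 1.71 ± 0.26, 0.000677) led. ARC, a serum response gene best known in neurons (1.11 ± 0.14, 4e-05), ZFP36, which speeds decay of cytokine transcripts (0.85 ± 0.15, 0.00547), and BTG2, which slows division (0.89 ± 0.18, 0.0125), followed. HES1, a Notch target repressor (1.51 ± 0.30, 0.0146), and NFKBIZ, a nuclear partner of NF-kB (0.72 ± 0.15, 0.02), were higher as well. PPP1R15A, which restarts translation after stress, was at 229 ± 57.7 against 138 ± 36.5 FPKM (0.75 ± 0.14, 0.00891). Of 28 listed immediate early genes, 5 were higher and 0 lower (11 over the list alone; list p 7.94e-13, 0.00642 with an estimated correlation). With pairing, 13 were higher and 1 lower (20 and 2 over the list alone; list p 2.39e-20, 0.0296), the lower one being the nuclear receptor NR4A3 (-0.54 ± 0.07, 3.14e-05).

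Some targets of p53 were higher at 2 h too, with BTG2 and the cell cycle inhibitor CDKN1A (210 ± 43.5 against 149 ± 15.9 FPKM, 0.51 ± 0.12, adjusted p 0.0349). Of 25 targets 2 were higher (5 over the list alone; list p 9.55e-05, but 0.631 with an estimated correlation). With pairing 5 were higher (7 over the list alone, 0.0455), including the death gene BBC3 (0.73 ± 0.11, 0.000618) and the stress cytokine GDF15 (0.61 ± 0.13, 0.0094). Lower on Matrigel were the cytokine CLCF1 (-0.64 ± 0.14, 0.0305), the golgin family gene GOLGA8A (-0.58 ± 0.14, 0.0438), SOCS6, a brake on receptor signalling (-0.56 ± 0.10, 0.00675), the kinase MAP3K2 (-0.55 ± 0.10, 0.00547), the chromatin reader GLYR1 (-0.53 ± 0.11, 0.0197), the sugar transferase OGT (-0.51 ± 0.12, 0.0435), the chromatin remodelling subunit SS18L1 (-0.51 ± 0.11, 0.0305), the zinc finger gene ZBTB1 (-0.49 ± 0.10, 0.02), FAM222B, whose role is little known (-0.47 ± 0.10, 0.021), and the SUMO protease SENP5 (-0.46 ± 0.09, 0.00891). GOLGA8A has close copies, so its reads may be shared. Genes lower on Matrigel had longer and more AT-rich transcripts (median 4640 bases, 44.3% GC) than those higher (2755.5 bases, 56.8%) or all tested (3166.5 bases, 49.8%). Of markers of other cells, the leukocyte integrin ITGAM (2.11 ± 1.27 against 0.778 ± 0.487 FPKM, paired 1.25 ± 0.31, 0.025) and the endothelial gene PECAM1 (paired 0.92 ± 0.20, 0.00905) were higher at a low level.

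With pairing, more genes differed at 2 h. Higher were TXNIP, which holds thioredoxin inactive (1.16 ± 0.14, adjusted p 2.44e-05), the differentiation inhibitor ID2 (1.00 ± 0.17, 0.00183), the stress factor DDIT3 (0.84 ± 0.16, 0.00341), the growth factor CSF3 (0.80 ± 0.11, 0.000164), the cytokine IL1A (0.53 ± 0.11, 0.00789) and the hypoxia-induced peptide ADM (0.71 ± 0.10, 0.000164). Lower were the S phase cyclin CCNE2 (-0.60 ± 0.07, 1.83e-05), the replication factor CDC6 (-0.30 ± 0.06, 0.00676), the basement membrane collagen COL4A1 (-0.43 ± 0.07, 0.000957) and the matrix glycoprotein THBS1 (-0.47 ± 0.10, 0.00588). Each went the same way in 3 of 3 pairs, which the naming rule required of the 10 highest and 10 lowest genes. Of 40 replication genes 8 were lower and 0 higher (11 over the list alone). That list was called, as were those for ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, collagens, NRF2 targets, autophagy, histones, glycolysis, cholesterol and vasculogenic mimicry, but all of these were lost with an estimated correlation (p of 0.0816 to 0.651). Without pairing, mitosis, glycolysis, ribosome biogenesis, vasculogenic mimicry and NRF2 lists were called and lost in the same way (0.622 to 0.848).

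In all, 99 genes differed at 2 h (42 higher, 57 lower on Matrigel) and 600 with pairing (196 and 404), of which 94 were shared. By DESeq2 there were 142 and 347 genes, and on log2(FPKM + 0.1) the unpaired split was 28 higher and 65 lower. The count depended on single libraries. Unpaired it was 61 without denatured replicate 1, 49 without Matrigel 1, 235 (74 higher, 161 lower) without denatured 2, 61 (42 and 19) without Matrigel 2, 16 (12 and 4) without Matrigel 3 and 34 (19 and 15) without denatured 4. It was 17 (15 and 2) without both replicate 3 libraries and 3 (3 and 0) when only these groups were fitted. The paired count was 292 when only these groups were fitted, 138 and 142 without either library of pair 1 and 64 (37 higher, 27 lower) without pair 3. Among all 35 ways to split the 7 libraries, 8 gave at least as many calls as the real one, and setting replicates 3 and 4 against 1 and 2 gave 2368, several times the real count, so a structure among the replicates was larger than the matrix difference.

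At 8 h, cells on Matrigel expressed more NRF2 targets and less of the cholesterol pathway, in the paired test only. HMOX1, which breaks down heme (chromosome 22, 35381096 to 35394207), was at 172 ± 32.1 against 89.4 ± 52.1 FPKM (paired 1.44 ± 0.18, adjusted p 0.000206). FPKM means on denatured Matrigel at 8 h include replicate 2, which has no partner and no weight in the paired values. NQO1, a quinone reductase (chromosome 16, 69709401 to 69726560), was at 230 ± 29.4 against 172 ± 29.6 (0.54 ± 0.05, 4.77e-06). The cystine carrier SLC7A11 (0.80 ± 0.15, 0.00857), OSGIN1, an oxidative stress gene (0.68 ± 0.12, 0.00779), GCLM of glutathione synthesis (0.55 ± 0.08, 0.0011) and the iron store FTH1 (0.43 ± 0.05, 8.46e-05) went the same way. So did TRIM16L (0.75 ± 0.10, 0.000303) and TRIM16 (0.40 ± 0.07, 0.00857), and whether they share reads was not checked. Of 21 NRF2 targets 11 were higher and 0 lower (15 over the list alone; list p 1.05e-41, 0.000111 with an estimated correlation). The stress factor ATF3 (1.01 ± 0.18, 0.00855) and GEM, a small GTPase (0.44 ± 0.10, 0.0299), were also higher. HMGCS1, an early enzyme of cholesterol synthesis, was at 17.5 ± 5.06 against 30.5 ± 9.49 FPKM (-0.60 ± 0.07, 3.91e-05), with MSMO1 (-0.41 ± 0.07, 0.00477), LSS (-0.37 ± 0.05, 0.000803) and DHCR7 (-0.34 ± 0.06, 0.0104) of the same pathway. In that list of 25, 12 were lower and 0 higher (21 over the list alone; 4.26e-40, 0.00145).

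**Figure D2:**
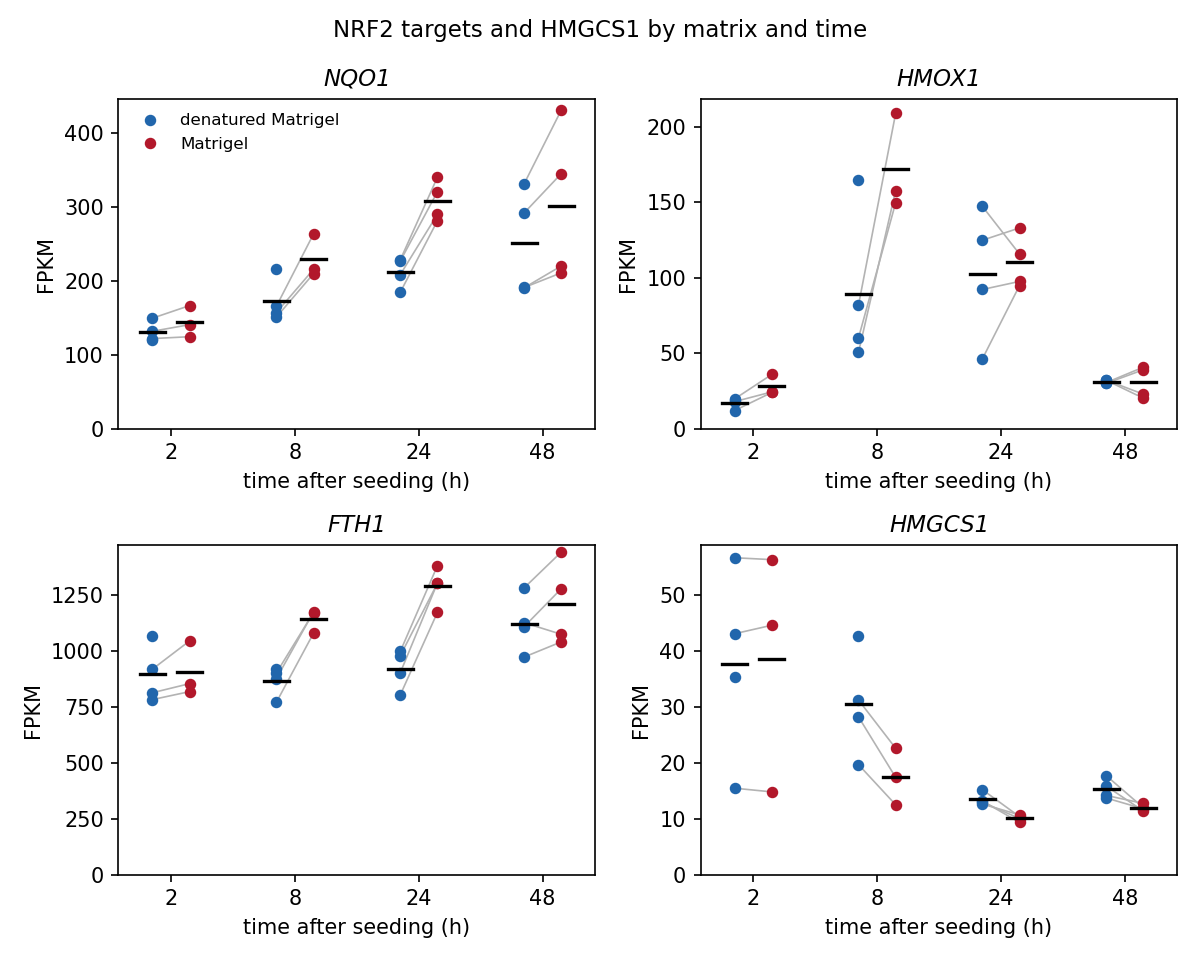
FPKM of 3 NRF2 targets (NQO1, HMOX1, FTH1) and of HMGCS1, an enzyme of cholesterol synthesis. Points are libraries, black bars are means and grey lines join same-number libraries.

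Cytoskeletal and inflammatory genes were lower on Matrigel at 8 h with pairing. TAGLN, an actin-binding protein of contractile cells (-0.81 ± 0.16, adjusted p 0.0109), CALD1, which binds actin and myosin (-0.43 ± 0.07, 0.00328), CNN2 (-0.39 ± 0.05, 0.000635) and cytoplasmic actin ACTG1 (-0.19 ± 0.04, 0.0405) led the focal adhesion list. Of its 31 genes 4 were lower and 0 higher (13 over the list alone; list p with an estimated correlation 0.00383). NF-kB targets lower were the adaptor TRAF1 (-0.92 ± 0.14, 0.002), the chemokine CXCL8 (-0.80 ± 0.13, 0.002), the survival gene BIRC3 (-0.77 ± 0.15, 0.0106) and NFKB2 (-0.44 ± 0.07, 0.00477), and 5 of 27 were lower with 0 higher (1 higher and 13 lower over the list alone; 0.046). The matricellular gene CTGF (-0.56 ± 0.11, 0.0124), the flow-sensing factor KLF2 (-0.68 ± 0.10, 0.00133), the vasoconstrictor EDN1 (-1.06 ± 0.22, 0.0203), the ephrin EFNB2 (-0.46 ± 0.07, 0.000995), the receptor PILRB (-0.55 ± 0.11, 0.0146), the scaffold AKAP12 (-0.49 ± 0.10, 0.0133), the clamp loader CHTF18 (-0.47 ± 0.09, 0.0133) and the immune ligand PDCD1LG2 (-0.46 ± 0.09, 0.0146) were lower too. Each was lower in 3 of 3 pairs, which the naming rule required of the 10 lowest genes.

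Without pairing 0 genes differed at 8 h by edgeR, with 298 genes at unadjusted p below 0.05, DESeq2 called 1 and limma 0, and the lowest adjusted p among the named genes was 0.252, for CALD1. With pairing 92 differed (24 higher, 68 lower). That count was 24 without either library of pair 1, 35 (17 higher, 18 lower) without pair 3, and 37 and 36 without the libraries of pair 4. It was 74 by DESeq2, 142 when only these groups were fitted and 151 without a low-count filter. Unpaired list tests called 14 lists. The focal adhesion list held with an estimated correlation (0.0109) and the other 13 did not (p of 0.152 to 0.865). With pairing 19 were called, and the 15 besides NRF2, cholesterol, focal adhesion and NF-kB were lost (0.0784 to 0.71). Exchanging labels within 3 pairs allows too few splits for a low share. The real split gave 92 and the highest other one 0.

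At 24 h NRF2 targets were again higher on Matrigel with pairing, and NF-kB, cholesterol and unfolded protein response genes were lower. AKR1C1, which reduces carbonyls and steroids, was at 14.2 ± 3.26 against 6.51 ± 1.6 FPKM (1.15 ± 0.13, adjusted p 4.81e-05), and AKR1C3 was higher by 0.59 ± 0.10 (0.00373). These AKR1C genes are close copies, so reads may be shared. NQO1 (308 ± 27.3 against 212 ± 20.4 FPKM, 0.56 ± 0.04, 1.18e-07), the ferritin chains FTH1 (0.51 ± 0.04, 4.46e-07) and FTL (0.45 ± 0.05, 9.84e-06), SLC7A11 (0.76 ± 0.13, 0.00233), OSGIN1 (0.58 ± 0.10, 0.00475) and TRIM16L (0.60 ± 0.08, 0.000298) were higher. Ferritin genes have many pseudogenes. Of 21 targets 14 were higher and 0 lower (18 over the list alone; list p 3.34e-64, 2.02e-05 with an estimated correlation). Unpaired, 0 passed over all genes and 15 over the list alone, and the list p was 5.3e-32 (0.00766). Between 8 and 24 h, 16 higher genes were shared (0.0706 by chance), including NQO1, FTH1, FTL, GSR, SRXN1 and TXNRD1, and 12 lower genes (0.363 by chance), including HMGCS1, TAGLN and TRAF1.

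Lower at 24 h with pairing were TRAF1 (-1.34 ± 0.19, adjusted p 0.000497), BIRC3 (-0.96 ± 0.13, 0.000351), NFKB2 (-0.45 ± 0.07, 0.00188) and, in 3 of 4 pairs, the NF-kB subunit RELB (-0.66 ± 0.14, 0.0204). Of 27 NF-kB genes 4 were lower and 0 higher (10 over the list alone; 0.0396 with an estimated correlation). HMGCS1 (-0.39 ± 0.06, 0.0011), SQLE (-0.24 ± 0.04, 0.00233) and the sterol-sensing factor SREBF2 (-0.19 ± 0.04, 0.0421) were among 4 of 25 cholesterol genes lower (16 over the list alone; 0.0348). The chaperones HSPA5 (-0.23 ± 0.05, 0.0409), HYOU1 (-0.24 ± 0.05, 0.00883), DNAJC3 (-0.24 ± 0.04, 0.00613) and HSP90B1 (-0.19 ± 0.04, 0.0336) were the 4 of 22 unfolded protein response genes lower (10 over the list alone; 0.0396). TAGLN (-0.87 ± 0.15, 0.00276), the inflammatory gene IL32 (-0.86 ± 0.15, 0.00494), the nuclear receptor coactivator PNRC1 (-0.61 ± 0.14, 0.0421), the hormone STC1 (-0.47 ± 0.08, 0.00249), ZSWIM4 (-0.46 ± 0.08, 0.00233), LENG8 (-0.45 ± 0.07, 0.00249), the autophagy receptor OPTN (-0.43 ± 0.06, 0.00043) and the glutamate carrier SLC1A3 (-0.42 ± 0.07, 0.00227) were lower. Higher were the sphingolipid receptor S1PR1 (0.51 ± 0.10, 0.0103), the hormone subunit CGB8, which has near-identical copies (0.46 ± 0.10, 0.0223), ACTG1 (0.31 ± 0.04, 0.000109), and ASNS (0.30 ± 0.06, 0.019) and PHGDH (0.29 ± 0.05, 0.00402) of amino acid synthesis.

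Without pairing 0 genes differed at 24 h by edgeR (379 at unadjusted p below 0.05), 9 by DESeq2, 6 when only these groups were fitted and 0 by limma. With pairing there were 107 (38 higher, 69 lower). The count was 54 without pair 1, 30 (15 and 15) without pair 2 and 65 without pair 3, and length and GC correction gave 148 (75 and 73). Both list tests called several lists that an estimated correlation did not keep. These were all but NRF2 of the 14 unpaired (p of 0.622 to 0.892) and 15 of the 19 paired (0.0816 to 0.676). Exchanging labels within 4 pairs gave 107 for the real split and 5 for the highest other, with too few splits for a low share.

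At 48 h, NRF2 targets remained higher on Matrigel with pairing. Some genes of the interstitial matrix and of hypoxia were lower, but both lists were lost with an estimated correlation (p 0.305 and 0.156). Fibronectin, FN1 (chromosome 2, 215360865 to 215436068), was at 644 ± 365 against 1082 ± 555 FPKM (-0.73 ± 0.10, adjusted p 0.000315), with the collagens COL1A1 (-0.71 ± 0.16, 0.0138) and COL6A3 (-0.60 ± 0.13, 0.0133), the adhesion protein TGFBI (-0.48 ± 0.11, 0.0177) and CTHRC1, a secreted collagen regulator (-0.64 ± 0.12, 0.00384). Of 18 interstitial matrix genes 1 was higher and 5 lower (2 and 8 over the list alone). The vessel growth factor VEGFA was at 12.8 ± 2.17 against 20.7 ± 6.80 FPKM (-0.63 ± 0.09, 0.000851), with MXI1 (-0.34 ± 0.08, 0.0149) and, in 3 of 4 pairs, NDRG1 (-0.48 ± 0.10, 0.00746) among 5 of 26 hypoxia genes lower (8 over the list alone). Other low genes were NREP of wound healing (-0.90 ± 0.11, 9.53e-05), the potassium channel KCNK3 (-0.90 ± 0.15, 0.00171), IL32 (-0.86 ± 0.18, 0.0088), SLC1A3 (-0.66 ± 0.06, 6.34e-06), YPEL3 (-0.62 ± 0.12, 0.0049), the sialic acid receptor SIGLEC15 (-0.59 ± 0.10, 0.00246) and the TGF beta target PMEPA1 (-0.55 ± 0.11, 0.00623). The interferon genes IFI44L (-0.79 ± 0.12, 0.000676), IFIH1 (-0.73 ± 0.13, 0.00313) and STAT2 (-0.27 ± 0.08, 0.0475) were 3 of 29 lower (3 over the list alone; p 0.305). The fibroblast marker FAP (-0.54 ± 0.10, 0.00526) moved with the collagens, and the leukocyte marker LAPTM5 was lower (-0.25 ± 0.05, 0.0105).

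**Figure D3:**
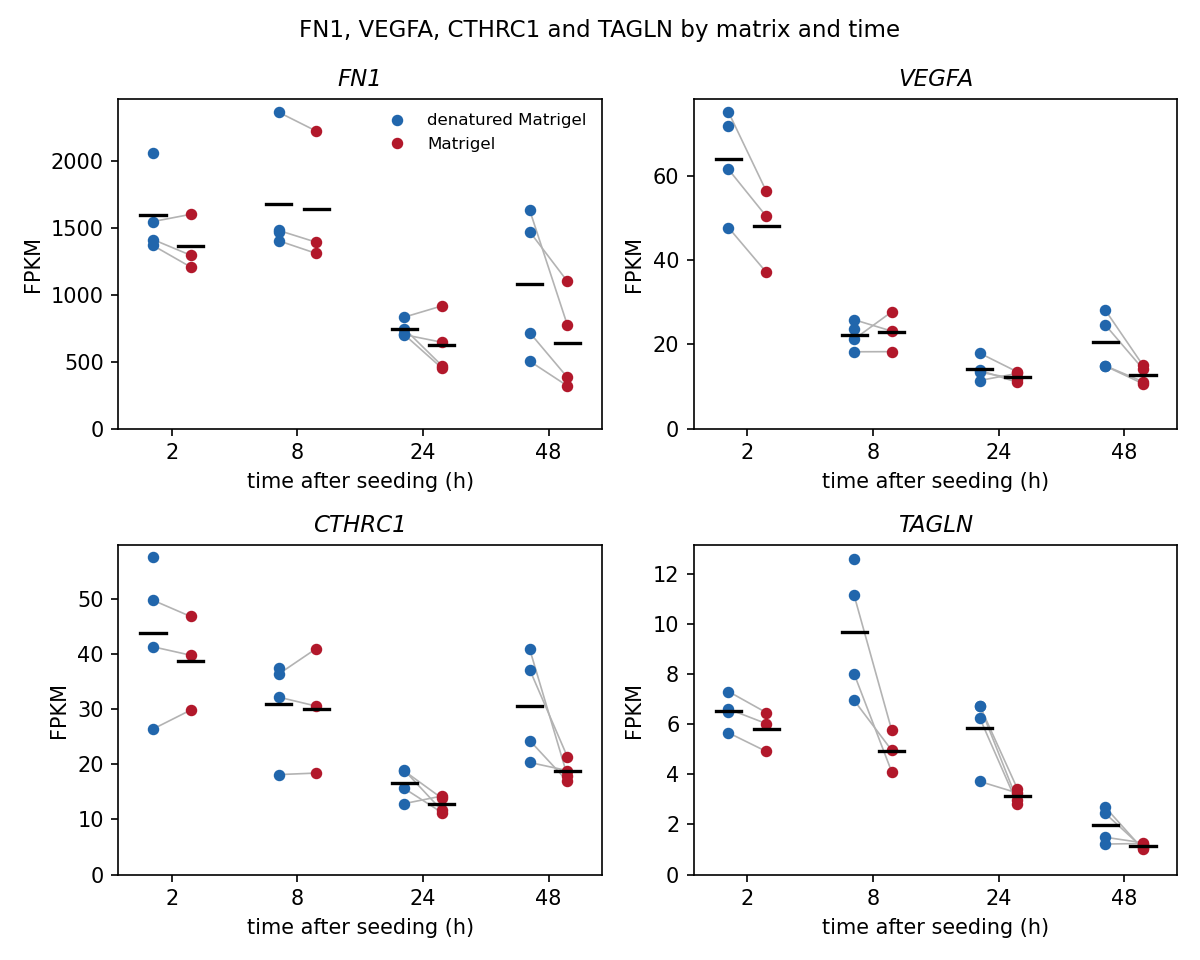
FPKM of fibronectin (FN1), VEGFA, the collagen regulator CTHRC1 and TAGLN. Points are libraries, black bars are means and grey lines join same-number libraries.

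Higher at 48 h with pairing were CGB8 (0.60 ± 0.10, adjusted p 0.00171), the surface protein CD24 (0.52 ± 0.13, 0.022), S1PR1 (0.49 ± 0.11, 0.0115), LY6K (0.47 ± 0.10, 0.0094), netrin NTN4 (0.46 ± 0.08, 0.00313), the RAB7 regulator TBC1D2 (0.44 ± 0.06, 0.000328), CCBE1, which activates VEGFC (0.42 ± 0.05, 9.53e-05), CXCL1 (0.41 ± 0.06, 0.000411), ADAP1 (0.38 ± 0.11, 0.0448; in FPKM not higher in pair 1, 7.72 against 7.8) and the transcription factor GATA2 (0.36 ± 0.08, 0.00976). Of YAP targets, the receptor AXL (0.28 ± 0.04, 0.000328), AMOTL2 (0.30 ± 0.06, 0.00404) and AJUBA (0.25 ± 0.06, 0.0133) were among 4 of 23 higher with 0 lower (6 over the list alone; p 0.373 with an estimated correlation). NQO1 (0.28 ± 0.04, 0.000941), FTL (0.21 ± 0.05, 0.0133) and, in 3 of 4 pairs, AKR1C1 (0.45 ± 0.12, 0.0286) were among 6 of 21 NRF2 targets higher with 0 lower (10 over the list alone; p 0.0385). Of 40 mitosis genes 11 were higher, such as CDC20 (0.21 ± 0.04, 0.0113) and AURKA (0.19 ± 0.04, 0.011), and 1 lower, the kinetochore gene CENPF (-0.23 ± 0.06, 0.0373; 19 and 3 over the list alone; p 0.256). Of 46 oxidative phosphorylation genes 7 were higher, such as CYC1 (0.21 ± 0.05, 0.0193), and 1 lower (15 and 1 over the list alone; p 0.457). Of 19 glycolysis genes 4 were higher, such as PGAM1 (0.15 ± 0.04, 0.0232), and 0 lower (8 over the list alone; p 0.295).

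Without pairing 0 genes differed at 48 h by edgeR (928 at unadjusted p below 0.05), 8 by DESeq2, 5 with an additive replicate block, 3 when only these groups were fitted, 1 with length and GC correction and 0 by limma. With pairing there were 587 (266 higher, 321 lower), a balance that did not hold. DESeq2 gave 381 (250 and 131), limma on log2(FPKM + 1) gave 393 (68 and 325) and on log2(FPKM + 0.1) 362 (63 and 299), a mean of at least 100 counts gave 566 (165 and 401), fitting only these groups gave 241 (42 and 199), and length and GC correction gave 1301 (964 and 337). The paired count was 128 and 125 without the libraries of pair 1, 1088 and 1087 without those of pair 2, 108 (32 and 76) without pair 3 and 365 (146 and 219) without pair 4. Unpaired list tests called 16 lists, none kept with an estimated correlation (p of 0.21 to 0.892). Of 20 paired lists only NRF2 was kept. Among splits within pairs the real one gave 587 and the highest other 140, too few splits for a low share.

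Genes tied to vasculogenic mimicry differed between the surfaces mainly with pairing, which called 3 higher and 1 lower at 2 h, 0 and 1 at 8 h, 0 and 1 at 24 h, and 2 and 3 at 48 h. Of 23 such genes 19 passed the low-count filter and were tested here, and FLT1, TEK, NODAL and FOXC2 did not pass it. Without pairing only TWIST1, a mesenchymal transcription factor, passed, at 2 h (10.6 ± 1.61 against 7 ± 0.528 FPKM, 0.60 ± 0.10, adjusted p 0.0035). With pairing, PECAM1 was higher at 2 h, and EPHA2, a kinase needed for such networks, was higher at 2 h (0.24 ± 0.05, 0.00416) and 48 h (0.16 ± 0.04, 0.021). The TGF beta co-receptor ENG was higher at 48 h (148 ± 2.15 against 134 ± 10.0 FPKM, 0.20 ± 0.04, 0.00916). VEGFA was lower at 2 h (-0.34 ± 0.10, 0.0447) and 48 h, where the matrix proteases MMP2 (-0.82 ± 0.19, 0.0154) and, in 3 of 4 pairs, MMP14 (-0.19 ± 0.05, 0.0461) were lower too. The vascular cadherin CDH5 (2.08 ± 1.36 against 1.75 ± 1.11 FPKM at 2 h), the receptors KDR and TIE1 (63.4 ± 3.31 against 60.3 ± 3.55 at 2 h), the clotting inhibitors TFPI and TFPI2, NOTCH4, SERPINF1, PTK2, PTGS2, HIF1A and EPAS1 passed in neither test at any time. Without pairing the list was called at 2 h (p 0.0251) and 48 h (0.0498), but at neither time with an estimated correlation (0.631 and 0.723).

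**Figure D4:**
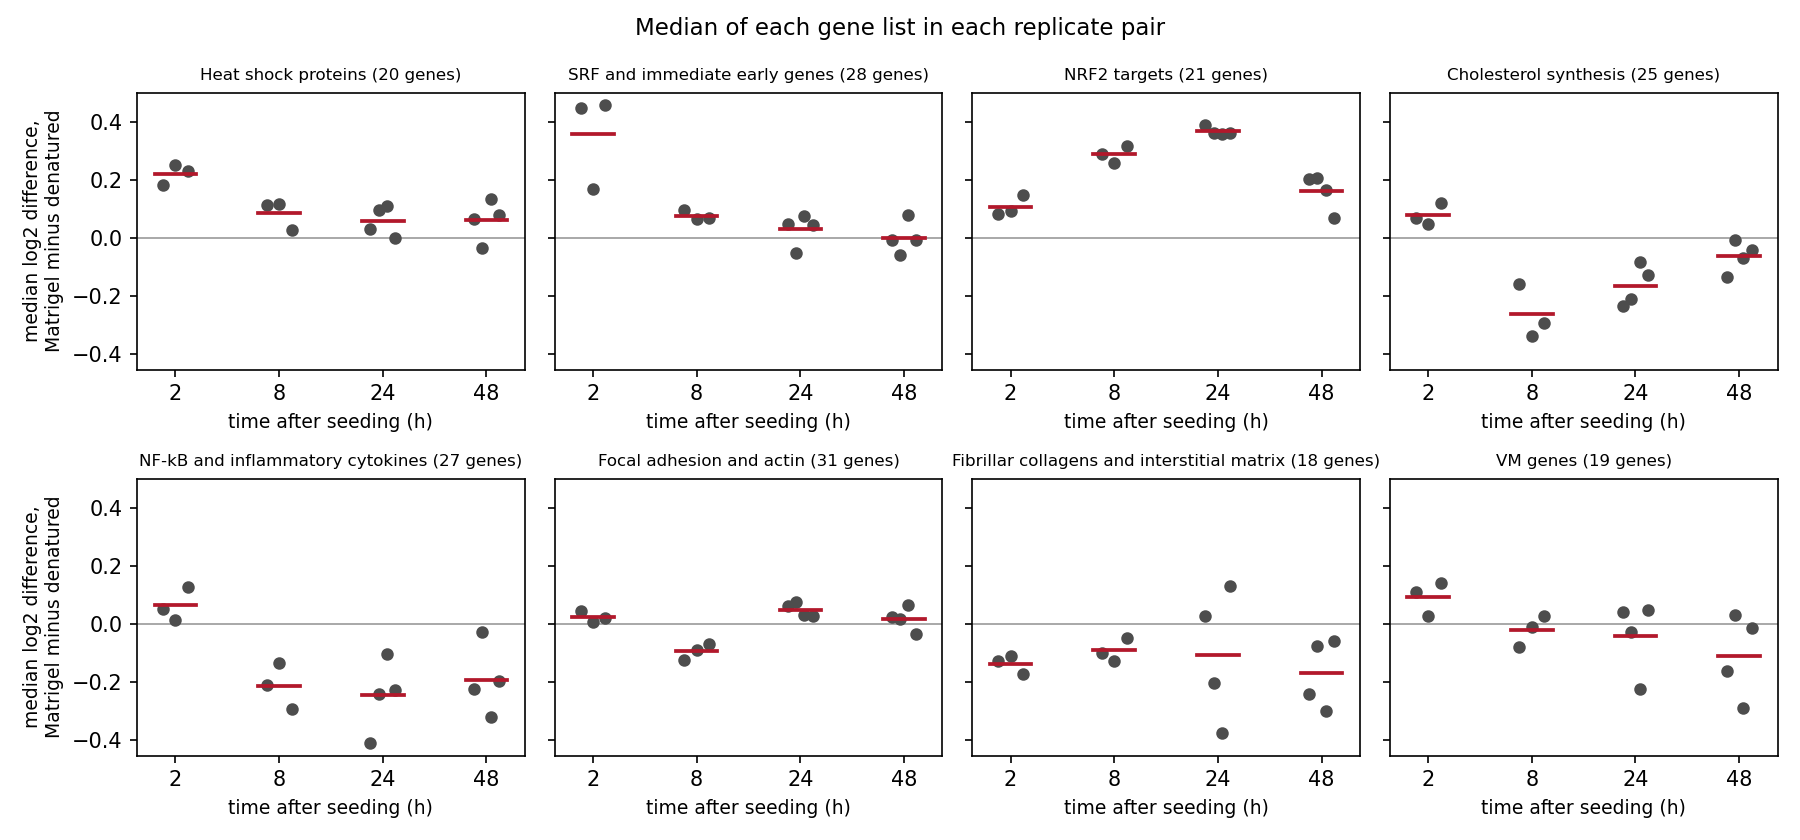
Median log2 difference, Matrigel minus denatured Matrigel, of 8 gene lists in each replicate pair. Points are pairs and red bars are means of pairs.

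The matrix difference of 3 HSP70 genes and ARC shrank from 2 to 8 h. HSPA6 changed by -6.45 ± 0.49 (adjusted p 2.77e-09), HSPA1A by -1.93 ± 0.22 (5e-06), HSPA1B by -1.93 ± 0.20 (1.72e-06) and ARC by -1.11 ± 0.20 (0.0151). For HSPA1A and HSPA1B this was not a fall on Matrigel, since their rise on denatured Matrigel over this step was larger than the change. With pairing the difference of CXCL8 moved down (-1.12 ± 0.16, 0.00113), and those of NR4A3 (1.36 ± 0.25, 0.00922), ZNF469, a collagen regulator (1.11 ± 0.14, 0.000349), SLC7A11 (1.01 ± 0.21, 0.0235) and PMEPA1 (0.73 ± 0.16, 0.0315) moved up. From 8 to 24 h with pairing, KLF2 (0.86 ± 0.13, 0.00462), PDCD1LG2 (0.68 ± 0.13, 0.0281), EFNB2 (0.56 ± 0.09, 0.00971) and CNN2 (0.50 ± 0.07, 0.00462) moved up, and HMOX1 (-1.22 ± 0.24, 0.0339) and SLC1A3 (-0.57 ± 0.10, 0.0162) down. From 24 to 48 h only CCBE1 (0.44 ± 0.07, 0.0308) and FTH1 (-0.37 ± 0.06, 0.0308) passed. When labels were exchanged within pairs, 3 of 32 splits from 2 to 8 h gave at least as many paired calls as the real one. For 8 to 24 h and 24 to 48 h these were 3 of 64 and 14 of 60, the real split included. The sterol carrier STARD4 was the only gene lower at all 4 times (-0.38 ± 0.06, -0.31 ± 0.07, -0.33 ± 0.06 and -0.41 ± 0.06 with pairing), and no gene was higher at all 4.

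In the unpaired test 8 genes changed their matrix difference at any time (522 at unadjusted p below 0.05; 21 by DESeq2), 5 without Matrigel replicate 1 at 2 h and 20 without denatured replicate 2 at 2 h. From 2 to 8 h there were 8 (0 up, 8 down), 17 (6 and 11) by DESeq2 and 7 (1 and 6) with length and GC correction, 4 without Matrigel replicate 1 and 23 without denatured replicate 2 at 2 h. For 8 to 24 h and 24 to 48 h there were 0, with 196 and 148 genes at unadjusted p below 0.05, and 0 by DESeq2 and limma. With pairing the counts were 301 at any time, 130 (60 up, 70 down) from 2 to 8 h, 13 (8 and 5) and 2 (1 and 1). At any time, paired counts were 129 on log2(FPKM + 0.1), 160 on log2(FPKM + 1), 574 with no low-count filter and 705 with length and GC correction. From 2 to 8 h, they were 64 (23 and 41) on log2(FPKM + 0.1), 198 (111 and 87) with length and GC correction and 241 with no low-count filter. From 8 to 24 h, they were 8 (6 and 2) on log2(FPKM + 1), 34 (25 and 9) with length and GC correction, 35 with no low-count filter and 37 when only these groups were fitted. From 24 to 48 h, they were 0 when only these groups were fitted, 1 by limma, 8 (5 and 3) with length and GC correction, 12 (8 and 4) by DESeq2 and 14 with no low-count filter. With 1 library left out, paired counts were 80 (without Matrigel replicate 1 at 2 h) to 567 (Matrigel 2 at 48 h) at any time, 19 (denatured 1 at 2 h) to 284 (Matrigel 2 at 2 h), 3 (denatured 4 at 8 h) to 17 (denatured 4 at 24 h) and 0 (denatured 1 at 24 h) to 12 (denatured 2 at 48 h).

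Up to 24 h, both surfaces shared most changes, and from 24 to 48 h most of the fewer changes on Matrigel also passed on denatured. From 2 to 8 h on Matrigel the endoplasmic reticulum genes SDF2L1 (9.20 to 71.7 FPKM, 3.00 ± 0.33, adjusted p 1.88e-08) and HSPA5 (189 to 1357, 2.88 ± 0.38, 3.28e-07) and the kinase SGK3 (2.82 ± 0.50, 2.38e-05) rose. The early genes FOSB (212 to 2.27 FPKM, -6.52 ± 0.27, 4.28e-16) and EGR3 (-5.84 ± 0.55, 1.03e-09) and the growth factor CSF2 (-5.77 ± 0.70, 6.91e-08) fell. On denatured Matrigel HSPA1A (37.5 to 320 FPKM, 3.13 ± 0.15, 3.44e-15), HSPA1B (3.08 ± 0.14, 1.15e-15) and SDF2L1 (2.76 ± 0.29, 3.42e-09) rose, and FOSB (-6.61 ± 0.24, 1.31e-17), NR4A3 (-6.46 ± 0.37, 6.54e-14) and EGR3 (-5.80 ± 0.52, 2.6e-10) fell. From 8 to 24 h CGB8 (2.95 ± 0.57 on Matrigel, 2.71 ± 0.52 on denatured) and the mitotic motor KIF20A (1.81 ± 0.18 and 1.92 ± 0.17) rose and the BMP antagonist GREM1 (-3.40 ± 0.30 and -3.14 ± 0.29) fell on both. The following also passed on both, with the value on Matrigel for the helicase PIF1 (1.82 ± 0.17), RRAD (-3.28 ± 0.34) and SCG5 (-3.14 ± 0.40), and on denatured for histone HIST1H3D (1.85 ± 0.34), PDGFB (-4.06 ± 0.54) and IL4I1 (-3.25 ± 0.52). From 24 to 48 h HMOX1 fell (-1.86 ± 0.31 and -1.76 ± 0.31) and PNRC1 rose (1.08 ± 0.20 and 1.07 ± 0.19) on both. The decoy receptor TNFRSF6B (1.24 ± 0.15), SHISA2 (0.97 ± 0.15), GCLM (-0.59 ± 0.14) and the cohesin guard SGO2 (-0.58 ± 0.15) are given on Matrigel, and SPP1 (1.72 ± 0.38), AKR1C1 (1.14 ± 0.29), TAGLN (-1.61 ± 0.21) and NAV2 (-0.90 ± 0.16) on denatured. All 8 moved the same way on the other surface, where SGO2, SPP1 and AKR1C1 did not pass.

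From 2 to 8 h 7702 genes changed on Matrigel (3801 up, 3901 down) and 8169 on denatured (3983 and 4186), of which 3363 rose and 3403 fell on both and 5 went opposite ways. From 8 to 24 h there were 4471 (2377 and 2094) and 4588 (2415 and 2173), with 1981 and 1606 shared; on log2(FPKM + 1) the splits were 2655 and 1508, and 2857 and 1512. From 24 to 48 h there were 150 (83 and 67) on Matrigel and 621 (300 and 321) on denatured, with 65 and 49 shared. On log2(FPKM + 1) these were 111 (79 and 32) and 475 (325 and 150), a mean of at least 100 counts gave 527 (327 and 200) on denatured, and no low-count filter gave 93 (64 and 29) on Matrigel. Higher counts came from an additive replicate block (460 on Matrigel, 1202 on denatured), from fitting only these groups (398 and 1587) and, on Matrigel, from DESeq2 (351). The 24 to 48 h counts moved with single libraries. On Matrigel they were 35, 29 and 33 without replicates 1, 2 and 4 of 24 h and 71, 18, 58 and 43 without replicates 1, 2, 3 and 4 of 48 h. On denatured they were 110, 171 and 90 without replicates 1, 2 and 4 of 24 h and 248, 139 and 141 without replicates 1, 3 and 4 of 48 h.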

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

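All splits, the length and GC correction and the tests of pairs (those at 2 h redefined after earlier forms of them were seen), of the shared time course, of depth and of paralogs were chosen after results were seen. Heat shock and immediate early genes were higher on Matrigel at 2 h (24 genes with pairing), and length and GC content does not explain this, since 20 of them still passed after correction. A single pair did not carry all of it, as over all 48 tested members of both lists the pair medians were 0.361, 0.192 and 0.33. Their lower 95% bounds were 0.193, 0.14 and 0.165. Whether the highest pair gave over 2 times the next could not be told (ratio of next to highest 0.912, 95% interval 0.491 to 1.49). Bounds and interval came from resampling the 48 genes as if independent, so they do not measure the spread between cultures. Matrigel cultures might merely be at an earlier point of a shared time course. Both groups were then predicted to fall from 2 to 8 h on denatured Matrigel, but heat shock members rose (median 0.991) while immediate early members fell (-1.27). An earlier point lies before 2 h, where no library was taken, so this decides only if the same trend held there. An earlier point thus stays open. The matrix itself remains the biological explanation given by the design, and a difference in handling between the surfaces was not tested.

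More genes were listed at 2 h (14853 to 15408 per library) than later (13971 to 14447). Greater depth was not the cause, since 2 h libraries held 16.2 M counts on average and later ones 17.1 M. Of 299 genes listed mainly at 2 h, 18.9% had an expressed neighbour upstream on the same strand against 10.7% of genes of the same count range, 8.11 points more (95% interval 3.47 to 13), so reads running past gene ends may add to it, but this could not be told. RNA from other cells stays open as well, since the 3 markers among these genes lay near the floor like the whole set (median 0.12 FPKM; highest marker APOA1, 0.151), so the bound set beforehand excluded nothing, and the endothelial genes CDH5 and PECAM1, outside the set, were higher at 2 h than at 8 h. Time in culture is the biological explanation the design gives for the difference between times. Within 2 h, Matrigel libraries listed more genes (15190 to 15408) than denatured ones (14853 to 15076). This difference between the surfaces was not tested.

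NRF2 targets were higher on Matrigel in pairs at 8, 24 and 48 h. Reads shared between copies of the AKR1 and ferritin genes do not explain all of it. The median of the 16 targets left after removing these genes was 0.257 at 24 h (all 21: 0.397), and 9 of the 16 were called. Shared reads may still add to its size. Length and GC content does not explain it at 24 h, with 14 targets still passing after correction. Nor does a single pair at 24 h, where the lowest of the 4 pair medians was 0.356. Pair medians were 0.256 to 0.317 at 8 h and 0.0688 to 0.207 at 48 h, times that these tests did not cover. The higher NRF2 targets may reflect the matrix, the only group difference in the design.

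Some single libraries lay far from the other 3 of their group, by the gap to the nearest library as a share of the group's range, above the critical value of Dixon's test. Of 530 groups of 4 libraries tested, 21 passed, and chance alone gives 26.5 at 1 in 20. At 2 h on denatured Matrigel these were GLYR1 (replicate 4 high, 0.848), the kinase regulator TRIB3 (4 high, 0.913), BBC3 (3 high, 0.923), PDGFB (3 low, 0.941) and MMP14 (3 low, 0.852). At 8 h on denatured Matrigel they were FOSB (4 low, 0.921) and CNN2 (4 high, 0.897). At 24 h on denatured Matrigel they were TAGLN (3 low, 0.838), the phosphatase DUSP5 (2 low, 0.872) and PHGDH (3 high, 0.876). At 24 h on Matrigel they were ACTG1 (3 low, 0.83), ACTB (3 low, 0.845), the p53 target TP53INP1 (3 high, 0.92), MMP2 (4 high, 0.842) and PTGS2 (1 high, 0.833). At 48 h they were ADAP1 (denatured 1 high, 0.884), TIE1 (denatured 2 low, 0.855), TWIST1 (denatured 3 low, 0.857), the number of genes listed (denatured 3 high, 0.845), CDC20 (Matrigel 1 high, 0.941) and EPAS1 (Matrigel 2 high, 0.886).

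The matrix difference of 5 named genes varied across the 4 times in the unpaired test of the difference: HSPA6 (adjusted p 1.29e-09), HSPA1A (5.67e-07), HSPA1B (4.52e-07), DNAJB1 (0.000936) and ARC (0.0391). With pairing 93 of those reported here did. Genes were named from these same data, some for a change between times, so many were bound to vary. Over all 12922 tested genes the paired count was 301, against 285 in the highest other split and 80 to 567 with 1 library left out. Heat shock genes were HSPA6 (8.58e-09), HSPA1A (6.32e-13), HSPA1B (6.21e-12), DNAJB1 (5.63e-10) and HSPH1 (0.000739), and endoplasmic reticulum chaperones were HSPA5 (0.0446) and HYOU1 (0.0446). Immediate early genes were EGR1 (0.016), FOS (0.0193), ARC (0.00528), ZFP36 (0.000739), NR4A3 (0.0223), DUSP1 (0.00231), DUSP5 (0.0373), KLF2 (0.000774), GEM (0.0113) and RRAD (0.0452). Stress, p53 and amino acid genes were PPP1R15A (0.00165), CDKN1A (0.0175), BBC3 (0.00169), GDF15 (0.0349), TXNIP (0.00156), ATF5 (0.0495) and SLC7A5 (0.00231). NRF2 targets and their neighbours were HMOX1 (0.00703), NQO1 (0.00102), FTH1 (0.00156), AKR1C1 (0.0218), SLC7A11 (0.0106) and TRIM16L (0.016). Cytokine, NF-kB and other immune genes were NFKBIZ (0.00381), CLCF1 (0.00813), CSF3 (0.000551), IL1A (0.0133), CXCL1 (0.000237), CXCL8 (0.00278), TRAF1 (0.0375), BIRC3 (0.0276), IL32 (0.0208), PDCD1LG2 (0.0208), IFI44L (0.00462), LAPTM5 (0.0325) and SIGLEC15 (0.0292). The signalling brake SOCS6 (0.0446) and the autophagy receptor OPTN (0.0452) varied too.

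Lipid genes whose paired difference varied across times were HMGCS1 (adjusted p 0.00325), MSMO1 (0.0162), LSS (0.0118), DHCR7 (0.0452), SREBF2 (0.0452) and SCD (0.0487). Vessel-related genes were TWIST1 (0.0084), PECAM1 (0.0428), VEGFA (0.0318), EPHA2 (0.0106), EFNB2 (0.00274), S1PR1 (0.0292), NTN4 (0.0378), CCBE1 (0.000739), ADM (0.00649) and STC1 (0.0265). Matrix, protease and TGF beta genes were THBS1 (0.016), FN1 (0.0334), LOXL2 (0.0446), ZNF469 (0.000529), ADAM15 (0.036), ADAM8 (0.00253), PMEPA1 (0.0223), TGIF1 (0.0452), CTGF (0.0439) and NREP (0.00703). Cytoskeletal, junction and YAP genes were ACTG1 (0.00025), ACTB (0.0167), CNN2 (0.0027), CLDN1 (0.0133), KRT7 (0.0159), AMOTL2 (0.00649) and AXL (0.0104). Cell cycle genes were CCNE2 (0.000213), CDC6 (0.0193), UHRF1 (0.0378) and AURKA (0.0352). Others were HES1 (0.00132), ZBTB1 (0.0103), SENP5 (0.0452), PNRC1 (0.00771), BHLHE40 (0.00771), NDRG1 (0.0323), MXI1 (0.0235), SLC1A3 (0.00011), TBC1D2 (0.00156), KCNK3 (0.0441) and YPEL3 (0.00331).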

How the results depend on the processing

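The correction for length and GC content, the runs without both replicate 3 libraries and the treatment of the paired fit as its own result were chosen after the data were seen. No result reversed. Of 391 results of named genes, 316 were past the threshold. Many lost it in single settings: 145 of 235 paired and 15 of 25 unpaired without both replicate 3 libraries, 846 of 2012 paired and 76 of 501 unpaired values with 1 library left out, 87 and 63 of 251 paired on log2(FPKM + 0.1) and log2(FPKM + 1), 68 of 251 paired and 23 of 65 unpaired with only the groups compared, and 24 of 214 with paired DESeq2. In each other setting at most 13 did. A further 106 changes of sign arose where neither value passed. In 45 cases DESeq2 gave no adjusted p. Quantile normalization was planned for data with FPKM only and was not run. At 15.62 M to 18.55 M counts, genes under the filter were left out of the main and paired fits. The fits with no low-count filter held 17348 genes. Where a count moved, the cause was not tested, except that fitting fewer groups leaves fewer residual degrees of freedom.

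The replicate block within time moved the matrix difference from 99 to 600 genes at 2 h, 0 to 92 at 8 h, 0 to 107 at 24 h and 0 to 587 at 48 h. It moved the changes from 8 to 301 at any time, 8 to 130 for 2 to 8 h, 0 to 13 for 8 to 24 h and 0 to 2 for 24 to 48 h, and called lists at 2 h from 8 to 14. With no replicate block these paired results were 99, 0, 0, 0, 8, 8, 0 and 0. The additive replicate block gave 5 at 48 h and, for 24 to 48 h, 460 on Matrigel and 1202 on denatured, against 150 and 621. It changed no other call count by over 1.5 times.

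With only the groups compared, the counts were 3 at 2 h, 6 at 24 h, 3 at 48 h, 3 for the change from 2 to 8 h, and 398 and 1587 for the steps from 24 to 48 h on Matrigel and denatured. With pairing they were 292 at 2 h, 142 at 8 h, 241 at 48 h, 37 for the change from 8 to 24 h and 0 from 24 to 48 h. Without both replicate 3 libraries, 17 were left at 2 h, and with pairing 64, 35, 65 and 108 at the 4 times. DESeq2 gave 1 at 8 h, 9 at 24 h, 8 at 48 h, 21 for any change, 17 for 2 to 8 h and 351 for the step from 24 to 48 h on Matrigel, and with pairing 347 at 2 h, 381 at 48 h and 12 for the change from 24 to 48 h.

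With no low-count filter, paired counts were 151 at 8 h, 574 for any change, 241 for 2 to 8 h, 35 for 8 to 24 h and 14 for 24 to 48 h, and the unpaired step from 24 to 48 h on Matrigel gave 93. Length and GC correction gave 1 at 48 h, and with pairing 1301 at 48 h, 705 for any change, 198 for 2 to 8 h, 34 for 8 to 24 h and 8 for 24 to 48 h. On log2(FPKM + 0.1) the paired counts were 362 at 48 h, 129 for any change, 64 for 2 to 8 h and 1 for 24 to 48 h. On log2(FPKM + 1) they were 160 for any change, 8 for 8 to 24 h and 1 for 24 to 48 h.

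With an estimated correlation, lists called went from 8 to 2, 14 to 1, 14 to 1 and 16 to 0 at 2, 8, 24 and 48 h, and with pairing from 14 to 3, 19 to 4, 19 to 4 and 20 to 1. With fry they were 2, 1, 1 and 0, and with pairing 6, 8, 7 and 8.

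Leaving out 1 library at a time gave, for the matrix difference, 16 to 235 genes at 2 h, 0 to 0 at 8 h, 0 to 0 at 24 h and 0 to 1 at 48 h, and with pairing 64 to 665, 24 to 91, 30 to 97 and 108 to 1088. Changes were 5 to 20 at any time, 4 to 23 for 2 to 8 h and 0 to 0 for the later ones, and with pairing 80 to 567, 19 to 284, 3 to 17 and 0 to 12. Steps on Matrigel were 6917 to 7325, 3500 to 4153 and 18 to 179, and on denatured 7711 to 8022, 3840 to 4396 and 90 to 899. Lists called were 8 to 14, 10 to 18, 7 to 16 and 10 to 18, and with pairing 13 to 16, 15 to 19, 9 to 24 and 17 to 24.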

Other observations

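The splits below were chosen after the results were seen. Of the 19 tested genes tied to vasculogenic mimicry, 11 changed from 2 to 8 h on Matrigel (1 rose, 10 fell) and 12 on denatured (3 and 9), then 11 (4 and 7) and 10 (4 and 6) from 8 to 24 h, and 0 on either from 24 to 48 h. From 2 to 8 h the endothelial genes PECAM1 (-3.67 on Matrigel, -2.58 on denatured) and CDH5 (-3.41 and -3.13), the prostaglandin enzyme PTGS2 (-2.88 and -2.04), the clotting inhibitor TFPI (-1.88 and -1.69), VEGFA (-1.03 and -1.48) and MMP14 (-0.70 and -0.50) fell, and EPAS1, a hypoxia factor, rose (0.70 and 0.64). TFPI rose again from 8 to 24 h (0.97 and 0.93) and EPAS1 fell (-1.17 and -1.34).

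Genes lower on Matrigel at both 2 and 48 h in the paired test numbered 33, against 10.0 by chance. They included LENG8, NKTR, PNN, LUC7L3, OGT and VEGFA. Genes lower at these times also had long transcripts (medians of 4715 and 4373 bases against 3166.5 for all), which the chance value leaves out of account, and no test of their functions was run. Between 24 and 48 h, 38 lower genes were shared (1.71 by chance) and 13 higher (0.782 by chance). The cytoplasmic actin ACTG1 was lower on Matrigel at 8 h and higher at 24 and 48 h.

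For the unpaired matrix difference at 2 h, 8 of 35 splits of the libraries, the real one included, gave at least as many calls as the real one (real 99, highest other 2368). At 8, 24 and 48 h the real count was 0, so that all 35 of 35 reached it by construction, which tests nothing; splits above 0 were 9 at 8 h (highest 665), 1 at 24 h (1) and 2 at 48 h (153, replicates 1 and 2 against 3 and 4). For lists called it was 27 of 35 at 2 h (8 and 16), 14 at 8 h (14 and 23), 6 at 24 h (14 and 17) and 3 at 48 h (16 and 20). Counts several times the real one point to a structure among the replicates. Changes gave 10 of 100 at any time (8 and 660), and 13 of 100 for 2 to 8 h (8 and 1013). For 8 to 24 h and 24 to 48 h the real count was again 0, which all 100 of 100 reach; 6 (highest 115) and 5 (24) lay above it.

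Time steps stood clear of other splits, 1 of 35 each, for 8 to 24 h on Matrigel (4471 and 2242) and denatured (4588 and 3), 24 to 48 h on Matrigel (150 and 0) and denatured (621 and 77), and 2 to 8 h on denatured (8169 and 1845). For 2 to 8 h on Matrigel the 10 splits were too few (7702 and 57). With exchange within pairs, splits were too few at 2 h (1 of 4, 600 and 0), 8 h (1 of 4, 92 and 0), 24 h (1 of 8, 107 and 5) and 48 h (1 of 8, 587 and 140). Paired changes gave 1 of 60 at any time (301 and 285), 3 of 32 for 2 to 8 h (130 and 314), 3 of 64 for 8 to 24 h (13 and 207) and 14 of 60 for 24 to 48 h (2 and 419).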
